A study of Arabidopsis thaliana with 10 samples.

How the data were processed

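PolyA RNA from the fifth true leaves of 4-week-old plants was sequenced in 10 libraries of 5 groups, 2 per group, grouped by the sample titles: wild type at 22 °C, Col-0 grown at 30 °C, unstressed progeny in generation 2 and in generation 3, and unstressed sgs3-12. Plants had spent their first week on plates before the move to 22 or 30 °C, with 16 h of light and 8 h of dark. Reads were aligned with HISAT2 2.0.4 to TAIR10 and assembled with StringTie 1.3.0, per the submitters' processing notes. The counting program, its settings and its handling of strand are not given in the sources used here. For that reason, values of overlapping genes and of near-identical copies are given as uncertain.

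The deposited table holds read counts per gene, which the authors made before deposit, in 10 columns named as counts per the file headers. It also holds deposited FPKM values (fragments scaled to transcript length and library size), in columns named as FPKM per the file headers. The headers do not say how these values were computed. One FPKM column name of the 30 °C-grown plants occurs 2 times and the other is missing, so those 2 FPKM columns were not used, and 8 were. Where FPKM was needed for the 30 °C-grown libraries it was computed from their counts and the gene length implied by the other columns, which 273 genes lack. Of 33602 gene IDs, 32835 were matched in the TAIR10 gene table used for names and coordinates.

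Differential expression was tested on the counts with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3), in a fit of all 10 libraries with group as the only factor, TMM scaling and edgeR's filterByExpr filter, which kept 19768 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The fit named in the design, made before the data were examined, was limma on log2(FPKM + 1) with a mean FPKM of 1 or more; since the file also held counts, the count model replaced it, and limma 3.58.1 became an alternative. DESeq2 1.42.0 was added as an alternative after the data were seen. Errors beside fold changes are standard errors, printed CPM are TMM-scaled, and n = 2 per group throughout.

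Each of the 4 groups was compared with wild type, and the 3 Col-0 generations with each other. Overlaps of called genes, and correlations of fold changes, were set against 20 simulated sets of unchanged groups, since every comparison uses the same 2 control libraries. All 10 libraries of a set, wild type included, were drawn gene by gene from the gene's mean over all libraries and its fitted spread. The groups of a set thus share 2 simulated controls, not the real wild-type counts. Fold changes against a group with 0 counts are given as "at least", with a floor of 3 counts over the group. Such floors and intervals cover counting error only.

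Gene lists were fixed before the data were examined: 30 lists with 428 entries and no gene in more than 1 list. They cover heat shock proteins, heat shock factors, the unfolded protein response, HTT genes, TAS2, TAS3 and TAS4 targets, TAS loci, RNA silencing, H3K27 methylation, flowering, warm-temperature growth and auxin, photosynthesis, the clock, salicylic acid, jasmonate, oxidative stress, cold and abscisic acid, senescence, flavonoids, glucosinolates, iron, phosphate, cell division, ATCOPIA78 copies, reference genes, and markers of meristem, root, guard cell, vascular and epidermal cells. The 28 lists with at least 3 tested members were tested with camera at a preset correlation between genes of 0.01, adjusted over lists within a comparison. Of the fixed members, those without enough counts were left out (for example 8 of 13 flavonoid and 4 of 11 meristem members were tested). Camera with an estimated correlation and fry were alternatives. For each list, calls were also counted with p adjusted over the list alone.

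Genes were to be named by a rule fixed before the data were examined. For each comparison it took the 8 largest positive and 8 largest negative fold changes among called genes with a mean FPKM of 1 or more and both libraries on the same side of both wild-type libraries. It added up to 4 called members of each list that passed or had 3 called members, the focal genes and the other TAS targets, and 10 genes per direction of the 3-generation overlap. Since edgeR called 0 genes (1564, 2302, 1696 and 1959 at an unadjusted p under 0.05 in 30 °C-grown plants, generation 2, generation 3 and sgs3-12, where DESeq2 called 278, 619, 191 and 592 and limma 1, 0, 0 and 5), the first part named none. In its place, the 10 DESeq2 calls per direction with the smallest edgeR p were named, a choice made after the values were seen, as was that of the other single genes named beside lists.

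The fits were tested on simulated data. With the spread fitted to this study and 200 of 19768 genes changed, edgeR recovered 0% of genes changed 2-, 4- or 8-fold, DESeq2 5.36%, 34.7% and 82.6% with 79 of 165 calls false, and limma 0%, 0% and 4.35%. With a dispersion of 0.01 for every gene, edgeR recovered 89.3%, 100% and 100%, with 6 of 200 calls false. In the simulated sets of unchanged groups DESeq2 made a mean of 35.7, 38.0, 37.4 and 34.1 false calls in the 4 comparisons with wild type.

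Alternatives planned before the data were examined were the pseudocount (0.1 and 0.5), the FPKM filter (0.1 or none), median-of-ratios and quantile scaling, robust fits, a replicate block, a fold threshold of 2, fits of only the 4 libraries compared, and leaving out each library in turn. Chosen after seeing the data were DESeq2, edgeR's newer quasi-likelihood method, median-of-ratios factors and no filter in edgeR, a gene length offset per library (lowess, span 0.3), the length slope and a clock index (mean log2 CPM of morning genes minus that of evening genes, from the libraries themselves) as covariates, and leaving out library 1 of generations 2 and 3. Gene ontology terms of 10 to 500 genes were tested on DESeq2 calls by a hypergeometric test. Total counts were 17674090 to 23145159 per library, so that the floor of 3 counts equals 0.130 to 0.170 CPM. Splits of samples were not counted because groups have 2 libraries, and small RNA and DNA methylation were not analysed here.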

Results

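PolyA RNA was sequenced from the fifth true leaves of Arabidopsis plants that were 4 weeks old. The 10 libraries fall into 5 groups of 2: wild-type Col-0 grown at 22 °C, Col-0 grown at 30 °C after the seedling stage (generation 1, below the 30 °C-grown plants), their unstressed descendants in generation 2 and in generation 3, and unstressed plants of the mutant sgs3-12. SGS3 is the RNA-binding partner of the polymerase RDR6 in the making of trans-acting small RNAs, which are cut from TAS transcripts. Total counts per library ranged from 17674090 to 23145159 over 33602 genes, of which 19768 had enough counts to test. Nothing in the labels says that the 2 libraries of a group came from separate plants or pools, so p-values measure only the spread between these samples, which may be technical.

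The libraries of a group agreed to different degrees. The correlation of log2 CPM (counts per 10⁶ counts, with TMM factors) across genes within a pair was 0.920 in wild type, 0.969 in 30 °C-grown plants, 0.788 in generation 2, 0.919 in generation 3 and 0.964 in sgs3-12. The biological coefficient of variation was 0.752 in the generation 2 pair and 0.472 over all groups. Library 1 of generation 2 and library 1 of generation 3 stood apart by gene length: log2 CPM changed by −2.13 and −1.16 per 10-fold of length, against −0.43 to 1.13 in the other libraries. In library 1 of generation 2, the 10% of genes with the shortest models (median 607 bp) lay 0.68 above their mean over all libraries and the longest 10% (median 4123 bp) lay at −1.48. The photosystem antenna gene LHCB1.3, the most abundant gene in 9 of the libraries (not in sgs3-12 library 2), took 1.56% to 4.65% of the counts there. Genes of the mitochondrial genome took 0.0246% and 0.0164% of the counts in the 30 °C-grown libraries, against 0.00182% to 0.00770% in the others.

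**Figure D1:**
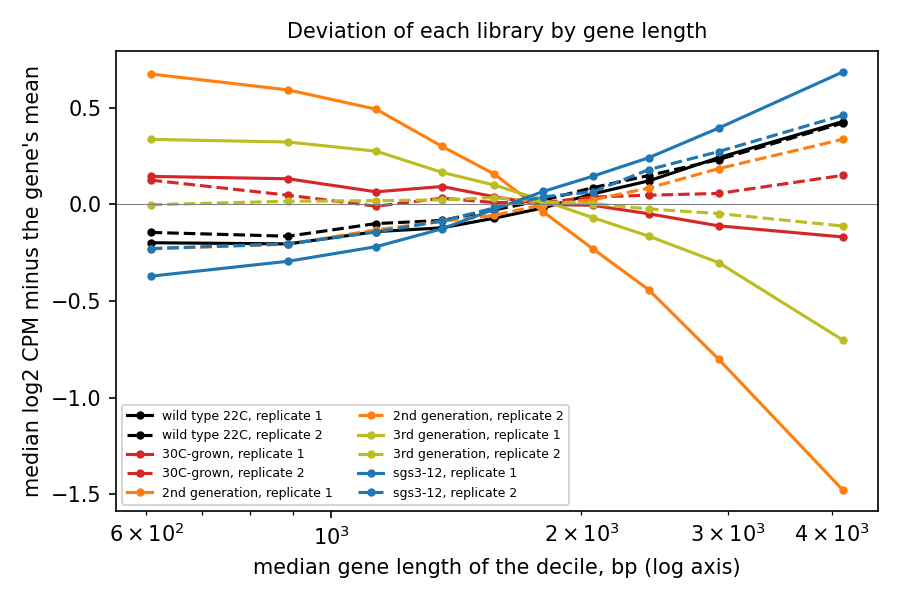
Median log2 CPM minus each gene's mean over the 10 libraries (y axis) for 10 classes of genes ordered by length (x axis, median length in bp, log scale), one line per library. Library 1 of generation 2 runs from 0.68 at 607 bp to −1.48 at 4123 bp, and library 1 of generation 3 from 0.34 to −0.70.

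SGS3 (AT5G23570, chromosome 5, 7943124 to 7946050, TAIR10) was measured in every sample as a check of the mutant. Its levels were 24.1 and 35.1 CPM in wild type, 25.4 and 21.01 in 30 °C-grown plants, 9.48 and 7.87 in generation 2, 14.1 and 15.2 in generation 3, and 9.40 and 8.02 in sgs3-12. Both sgs3-12 libraries lay below both wild-type libraries, with a log2 fold change of −1.76 ± 0.34 (SE, n = 2 per group, edgeR adjusted p = 0.280). Generation 2 was as far below wild type, at −1.77 ± 0.34 (edgeR adjusted p = 0.357), and generation 3 lay at −1.01 ± 0.33 and 30 °C-grown plants at −0.35 ± 0.33. DESeq2 called SGS3 in sgs3-12 (adjusted p = 0.000234) and in generation 2 (0.000379), and over all alternatives run its adjusted p ranged from 1.83e-05 to 1 in sgs3-12 and from 0.000379 to 0.985 in generation 2. The position of the sgs3-12 lesion is not given in the sources used here.

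**Figure D2:**
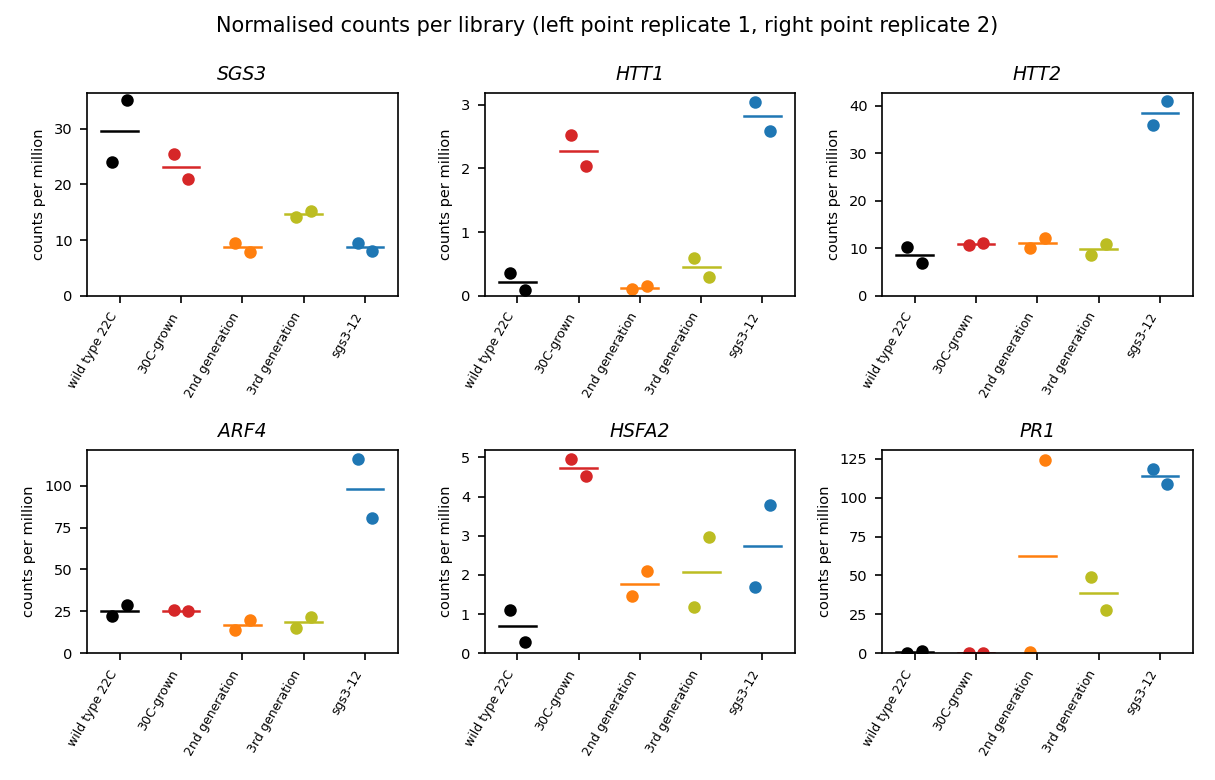
Level in CPM (y axis) of SGS3, HTT1, HTT2, ARF4, HSFA2 and PR1 in each of the 10 libraries (points) by group (x axis), with the group mean as a line. SGS3 lies at 7.87 to 9.48 CPM in generation 2 and sgs3-12, and HTT2 at 35.9 and 41.1 CPM in sgs3-12 against 6.999 to 12.1 in the other groups.

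The first comparison, 30 °C-grown plants against wild type at 22 °C, addresses the response to growth in the heat. Transcripts of heat shock proteins, which refold or hold damaged proteins, stood at 13.9 times the wild-type level for HSP17.6A-CI (AT1G59860, chromosome 1, 22031413 to 22032132): 15.1 and 17.0 CPM against 1.15 and 1.16, a log2 fold change of 3.79 ± 0.58 (SE, n = 2 per group). HSP70-4 (AT3G12580, chromosome 3, 3991261 to 3993792) was at 279.9 and 360.1 CPM against 8.71 and 9.04 (5.17 ± 1.59). HSP23.5 was at 21.2 and 21.01 against 0.486 and 0.973 (4.85 ± 0.99), and the co-chaperone gene HOP3 at 31.3 and 64.5 against 2.17 and 2.36 (4.40 ± 1.39). The vegetative storage protein gene VSP2 (AT5G24770), a jasmonate marker, was at 692 and 406 CPM against 8.75 and 48.2 (4.27 ± 1.18). At lower levels were the transposable element gene AT4G04410 (chromosome 4, 2189515 to 2193763; 1.01 ± 0.19 CPM against 35.6 ± 17.43, mean ± SD, log2 fold change −5.13 ± 0.52) and the receptor kinase gene AT3G46370 (chromosome 3, 17051955 to 17055514; 6.56 against 57.0 CPM, −3.12 ± 0.36).

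At an adjusted p under 0.05, edgeR's quasi-likelihood test called 0 of the 19768 genes, with 1564 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.138, for AT4G04410. DESeq2 called 201 genes higher and 77 lower, and limma on log2(FPKM + 1) called 1. On counts simulated for this comparison with the fitted spread and 200 changed genes, edgeR recovered 0 of them, and DESeq2 recovered 82.6% of those changed 8-fold while 79 of its 165 calls were false. Leaving out library 1 of generation 2, edgeR called 34 genes here, 19 without library 2 of generation 2 and 1 without library 2 of wild type. Both 30 °C-grown libraries lay above both wild-type libraries for 26.3% of the genes and below both for 25.2%, against 16.7% by chance.

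Among DESeq2 calls with the smallest edgeR p (edgeR adjusted p = 0.398 for each of those named next), genes at higher levels were SCPL7, a serine carboxypeptidase-like gene (AT3G10450, chromosome 3, 3249526 to 3252506; 28.6 against 5.86 CPM, 2.28 ± 0.34) and BT5, a BTB/TAZ domain gene (AT4G37610, chromosome 4, 17670481 to 17672353; 102 and 98.6 against 8.36 CPM on average, 3.58 ± 0.61). Next came RTFL5 (8.16 against 0.773 CPM, 3.39 ± 0.57), AT2G04795 (11.1 against 2.18 CPM, 2.35 ± 0.42). The mitochondrial genes ATP9 (ATMG01080; 55.9 against 4.41 CPM, 3.66 ± 0.63) and ORF262 (ATMG01090; 15.4 against 1.38 CPM, 3.47 ± 0.59) were higher in the libraries with the larger mitochondrial share. AT2G07811 (3.15 ± 0.55) and AT2G07774 (3.39 ± 0.56) lie on chromosome 2, in a stretch near-identical to mitochondrial DNA, so their values are uncertain. The RING finger gene ATL74 (AT5G01880, chromosome 5, 338899 to 340253) had 0 counts in wild type, but it overlaps AT5G01881, and summed with that gene it was at 5.20 times the wild-type level (edgeR adjusted p = 0.483). At lower levels were AT3G29320, the plastid starch phosphorylase PHS1 (chromosome 3, 11252807 to 11257814; 124 against 574 CPM, −2.21 ± 0.44) and the flippase gene ALA8 (−2.38 ± 0.41). So were AT3G16670 (−3.12 ± 0.53), AT4G13572 (−2.57 ± 0.46), and CXE2, with 0 counts in 30 °C-grown plants (at least 13.5-fold lower). The overlapping pairs AT4G13495 (−3.21 ± 0.49) with MIR850A (−2.79 ± 0.45), and ATG4A (−2.24 ± 0.40) with AT2G44130, cannot be separated. limma's only call, the cupin gene AT4G36700 (3.49 ± 0.27, limma adjusted p = 0.0213), was at 22.4 and 16.9 CPM against 0 and 0.417, with an edgeR adjusted p of 0.451.

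As groups, 9 of the 28 gene lists tested rose against the other genes by camera with its preset correlation of 0.01, and edgeR called 0 members of any list over all genes. None of these calls held with an estimated correlation, where 7 of the 9 had an adjusted p of 0.503. That form of camera called 0 lists in all 4 comparisons. This includes the HTT list, whose estimated correlation was negative (−0.044 here and −0.024 in sgs3-12). The form with an estimated correlation also tests on the residual degrees of freedom of the fit, which are few with 10 libraries in 5 groups. The preset form does not have this limit. Losses with an estimated correlation therefore cannot be put down to correlation between genes alone. All 30 heat shock protein genes were expressed, 26 with a positive fold change and 23 above both wild-type libraries. Their median log2 fold change was 2.35 (camera adjusted p = 9.98e-14, adjusted p = 0.503 with an estimated correlation), and 4 were called adjusted over the list alone. DESeq2 called 5 of them higher, and HSP90.1 (3.67 ± 1.34) and HSP101 (1.45 ± 0.77) were not among those. Of the heat shock factors, 16 of 21 were testable, with a median of 0.55 (camera adjusted p = 0.0464, adjusted p = 0.503 with an estimated correlation). HSFB2A (AT5G62020, chromosome 5, 24916089 to 24917643) was the member called over the list alone (25.3 and 17.42 against 6.01 and 5.10 CPM, 1.94 ± 0.35). HSFA2 (AT2G26150, chromosome 2, 11135682 to 11137396), which sustains heat tolerance, was at 4.96 and 4.52 against 1.105 and 0.278 CPM (2.76 ± 0.78, edgeR adjusted p = 0.494). The call of this list was kept in 1 of 10 fits that left out 1 library, the one without library 2 of generation 2. Over these fits camera adjusted p ranged from 0.0489 to 0.229. It was 0.229 and 0.0690 without wild-type library 1 or 2, and 0.0746 and 0.0573 without 30 °C-grown library 1 or 2. It was 0.0528 without generation 2 library 1, 0.0646 and 0.0641 without generation 3 library 1 or 2, and 0.0568 and 0.0567 without sgs3-12 library 1 or 2.

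Jasmonate and wounding genes had a median of 1.75, with 18 of 19 positive and 15 above both wild-type libraries (camera adjusted p = 2.02e-07, adjusted p = 0.503 with an estimated correlation, 0 adjusted over the list alone). VSP1 was at 346 and 141 CPM against 0.619 and 28.2, and the repressor gene JAZ9 at 379 and 244 against 44.7 and 61.6. All 11 iron deficiency genes were positive, with a median of 2.00 (camera adjusted p = 6.61e-07, adjusted p = 0.503 with an estimated correlation, 0 adjusted over the list alone). Several were at 0 in wild-type library 1 alone: the regulator BHLH39 was at 0 and 17.38 CPM in wild type and 58.8 and 53.4 in the heat, and the peptide gene IMA1 at 0 and 14.0 against 35.2 and 42.5. Without that library the camera adjusted p of this list was 0.0649 (range over the 10 fits 1.49e-22 to 0.0649).

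Glucosinolate synthesis (median 0.71, 11 of 15 positive, camera adjusted p = 0.00865, adjusted p = 0.503 with an estimated correlation) held BCAT4 at 621 and 503 CPM against 135 and 232. Senescence genes had a median of 0.84, 14 of 16 positive (camera adjusted p = 0.00865, adjusted p = 0.503 with an estimated correlation), with SAG21 at 87.5 and 54.0 against 4.16 and 9.36 CPM. The unfolded protein response of the endoplasmic reticulum had a median of 0.77, 10 of 12 positive (camera adjusted p = 0.0267, adjusted p = 0.796 with an estimated correlation), with ERDJ3A at 6.46 and 6.30 against 1.15 and 1.90 CPM. Phosphate starvation genes had a median of 0.87, 9 of 9 positive (0.0334 by camera, adjusted p = 0.503 with an estimated correlation). In these 4 lists 0 members were called adjusted over the list alone. All 4 calls were lost without wild-type library 1, at camera adjusted p of 0.0869, 0.265, 0.229 and 0.567 in that order. Those of senescence and phosphate were also lost without 30 °C-grown library 1 (0.0958 and 0.0668) and that of the unfolded protein response without library 2 (0.109). Over the 10 fits their camera adjusted p ranged from 0.00836 to 0.0869, 0.000188 to 0.265, 0.0123 to 0.229 and 1.40e-05 to 0.567.

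With a clock index as covariate, 3 calls of this comparison were lost, those of heat shock factors (camera adjusted p = 0.159), the unfolded protein response (0.189) and glucosinolates (0.173). Phosphate was lost with the length slope as covariate (0.196). Without library 1 of generations 2 and 3, heat shock factors and phosphate were lost (0.0707 for each, and 0.0638 and 0.0523 with a length offset as well).

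The HTT genes, which are targets of TAS1 small RNAs and are known for their part in heat tolerance, rose as a group. Their median was 1.55 with 5 of 5 positive (camera adjusted p = 0.00310, adjusted p = 0.443 with an estimated correlation), and 1 was called adjusted over the list alone. HTT1 (AT4G29770, chromosome 4, 14575718 to 14577643) was at 2.53 and 2.03 CPM against 0.354 and 0.0927, a log2 fold change of 3.31 ± 0.73 (edgeR adjusted p = 0.416, called by DESeq2). HTT2 was at 10.9 against 8.58 CPM (0.34 ± 0.33) and HTT3 at 3.52 against 1.199 (1.55 ± 0.56), while HTT4 was at 0 and 0.423 against 0.0442 and 0.139 CPM, and HTT5 at 0.146 and 0.296 against 0, at least 3.25-fold. These genes are related in sequence, and how shared reads were counted is not given in the sources used here, so single members are uncertain.

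The flowering list did not pass by camera (median 0.04 with a mean and test downward, camera adjusted p = 0.484). It passed fry's mixed test, which takes changes in both directions (fry adjusted p = 0.00268), as did heat shock factors (0.00470) and the HTT list (0.00464). Of its genes, 7 members were called adjusted over the list alone, 1 higher and 6 lower. The flowering promoter SPL4 was at 1.99 and 2.24 CPM against 13.6 and 6.86 (−2.27 ± 0.46), the repressor gene SNZ at 5.44 and 4.74 against 45.5 and 9.73 (−2.44 ± 0.63), and GI at 16.9 and 19.96 against 42.9 and 146. Of 12 oxidative stress genes (median 0.14, camera adjusted p = 0.286), 3 were called adjusted over the list alone, 2 higher and 1 lower. The catalase CAT1 was at 22.8 and 24.6 CPM against 115 and 104 (−2.21 ± 0.60). The ascorbate peroxidase APX2, known as a heat marker, was at 1.26 and 1.69 against 0 and 0. Camera adjusted p was 0.286 for photosynthesis (median −0.34), salicylic acid and immunity (−0.44, or −0.34 with zero groups at their bound) and cold and abscisic acid response (−0.49). It was 0.224 for the clock (−1.15), 0.302 for H3K27 methylation and demethylation (−0.45). It was 0.484 for RNA silencing (−0.33), cell division (0.05, with a mean and test downward), meristem markers (1.11, or 0.47 at the bound) and flavonoid synthesis (0.23, or −0.00 at the bound). PR1 was at 0.0486 CPM (1 count) and 0 against 0 and 1.34.

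The second comparison, generation 2 against wild type, addresses what remained different in unstressed progeny of heat-grown plants. Genes of starch breakdown were among those at lower levels. PHS1 (AT3G29320) was at 53.5 and 48.3 CPM against 588.8 and 559.5, a log2 fold change of −3.50 ± 0.46 (SE, n = 2 per group). The glucan water dikinase GWD1 (AT1G10760, chromosome 1, 3581034 to 3590928) was at 31.01 and 55.4 against 403 and 1480 (−4.45 ± 0.71), and the pullulanase PU1 (AT5G04360, chromosome 5, 1221566 to 1228678) at 12.1 and 12.0 against 53.4 and 73.1 (−2.39 ± 0.41). AT3G46370 lay at 10.8 against 57.0 CPM (−2.40 ± 0.35) and the xylosidase gene XYL1 at 111 against 517 (−2.22 ± 0.36). The lectin-like gene LEC (AT3G15356, chromosome 3, 5174402 to 5175469) was at 79.2 and 170.1 CPM against 13.2 and 13.4 (3.23 ± 0.52). HSFB2A was at 18.1 and 20.7 against 6.01 and 5.10 (1.80 ± 0.35), and the calmodulin-like gene CML9 at 256 and 370.0 against 97.3 and 64.3 (1.95 ± 0.39).

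edgeR's quasi-likelihood test called 0 genes at an adjusted p under 0.05 and found 2302 at an unadjusted p under 0.05, with an adjusted p of 0.357 for each gene named in the previous sentences. DESeq2 called 438 higher and 181 lower, and limma called 0, with 1915 genes at an unadjusted p under 0.05. The count of edgeR calls rested on which library was kept. It was 1637 (51 higher, 1586 lower) without library 2 of generation 2, 764 (715 higher, 49 lower) without library 1, and 1 without wild-type library 2, the lone library being assumed to vary like the other groups. Both libraries lay above both wild-type libraries for 16.8% of the genes and below both for 17.2%, against 16.7% by chance.

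Other DESeq2 calls with small edgeR p were AT4G21740 (19.9 ± 0.47 against 5.21 ± 0.95 CPM, mean ± SD, 1.93 ± 0.31) and the ubiquitin ligase gene PUB20 (7.91 and 35.1 against 1.59 and 1.62 CPM, 3.74 ± 0.68). Others were AT1G72940 (1.74 ± 0.34), AT2G41110 (2.18 ± 0.44) and AT3G18560 (2.45 ± 0.50). The genes ATL74 and CPuORF49 had 0 counts in wild type, but both overlap another gene, AT5G01881 and HSFB1, and summed with it they were at 7.13 and 4.91 times the wild-type level. At lower levels were AT3G01310 (19.4 against 198 CPM, −3.35 ± 0.53), AT3G05130 (0.776 against 16.3 CPM, −4.39 ± 0.74), AT1G63240 (−2.42 ± 0.40), emb2746 (−2.80 ± 0.51) and IBS1 (−1.73 ± 0.32). HTT1 was at 0.112 and 0.146 CPM against 0.354 and 0.0927 (−0.76 ± 0.82), HTT2 at 11.1 against 8.58 (0.37 ± 0.33) and HTT3 at 1.01 against 1.199 (−0.26 ± 0.56). HTT4 was at 0 and 0.0486 CPM, and HTT5 at 0 and 2.19 against 0 (at least 16.1-fold, from library 2 alone).

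Of the 28 lists, 5 passed by camera, all with an adjusted p of 0.808 with an estimated correlation. The 22 tested genes of RNA silencing fell as a group, with a median of −0.94, 19 negative and 12 below both wild-type libraries (camera adjusted p = 7.76e-06, adjusted p = 0.808 with an estimated correlation). Over the list alone 2 were called lower, SGS3 and the Argonaute gene AGO10 (8.35 and 13.2 against 33.1 and 38.6 CPM, −1.73 ± 0.40), and RDR6 was at 3.70 and 15.696 against 30.2 and 26.9 (−1.56 ± 0.59). Without library 1 of generation 2, the one with the steep length trend, the list's camera adjusted p was 0.125 (range over the 10 fits 4.92e-09 to 0.125). With a length offset it was 0.0217, with the length slope as covariate 0.366, and without library 1 of generations 2 and 3 it was 0.124 (0.151 with an offset as well; range over 5 alternatives 5.09e-07 to 0.366). Salicylic acid and immunity genes had a median of 2.16, 26 of 30 positive but 3 above both wild-type libraries (camera adjusted p = 0.000415, adjusted p = 0.808 with an estimated correlation). WRKY53 was at 4.54 and 162 CPM against 2.56 and 1.76, WRKY46 at 5.05 and 66.2 against 3.32 and 1.95. EDS5, which exports salicylic acid from the chloroplast, was at 2.07 and 43.6 against 1.81 and 1.53, and PR1 at 0.505 and 124 against 0 and 1.34. Jasmonate genes had a median of 3.24, 18 of 19 positive but 4 above both (camera adjusted p = 0.000415, adjusted p = 0.808 with an estimated correlation). The lipoxygenase gene LOX3 was at 8.75 and 870.2 CPM against 21.04 and 14.9 and LOX4 at 1.40 and 627 against 3.71 and 3.80. Senescence genes had a median of 0.91 (camera adjusted p = 0.00259, adjusted p = 0.808 with an estimated correlation), with NAP at 38.2 and 164 CPM against 21.2 and 9.55. Flavonoid genes had a median of 1.93 (camera adjusted p = 0.00952, adjusted p = 0.808 with an estimated correlation), with F3H at 4.99 and 83.7 against 6.54 and 2.64. These last 4 lists had 0 members called adjusted over the list alone, and DESeq2 called 8, 8, 4 and 0 higher in that order.

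Those 4 calls rested on library 2 of generation 2, without which camera adjusted p was 0.230, 0.697, 0.316 and 0.354 in the same order. Without wild-type library 1 the first 3 were also lost (0.145, 0.544 and 0.235), and the flavonoid call was lost without wild-type library 2 (0.1002). Over the 10 fits these camera adjusted p ranged from 1.56e-25 to 0.230, 1.54e-15 to 0.697, 5.35e-06 to 0.316 and 0.00211 to 0.354. With a clock index as covariate the jasmonate and flavonoid calls were lost (0.108 and 0.727). Of 20 clock genes (median −1.61, camera adjusted p = 0.0675), 10 were called adjusted over the list alone, 2 higher and 8 lower, beside a wild-type pair that itself differed. ELF3 was at 5.61 and 3.60 CPM against 18.3 and 79.1. Adjusted over the list alone there were also 1 higher heat shock factor (HSFB2A), 2 oxidative stress genes (ZAT10 higher, CAT3 lower) and 1 lower flowering gene, GI, at 3.645 and 11.2 CPM against 42.9 and 146. The heat shock protein list had a median of 0.56 (camera adjusted p = 0.578), the unfolded protein response 0.35 (0.822), and heat shock factors 0.33 (0.182). Medians were, for the HTT list, −0.26 with a mean and test upward (0.958), iron deficiency −3.22 with 0 of 11 positive (0.0638), and phosphate −0.66 (0.292), and for H3K27 −0.50 (0.0827), photosynthesis 0.31 (0.231) and glucosinolate 0.25 (0.822). They were, for cold and abscisic acid, 0.43 with a mean downward (0.958), cell division −0.35 (0.132) and meristem markers 2.93, or 1.63 at the bound (0.0596).

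The third comparison set generation 3 against wild type, a further generation after the heat. PHS1 (AT3G29320) was at 67.2 and 55.5 CPM against 588.8 and 559.5 (−3.23 ± 0.46, SE, n = 2 per group). GWD1 was at 56.9 and 40.7 against 403 and 1480 (−4.27 ± 0.70), AT5G40450 at 42.3 and 25.8 against 583.4 and 653 (−4.18 ± 0.67). The co-chaperone gene BAG6 (AT2G46240, chromosome 2, 18986133 to 18989947) was at 0.796 and 0.486 against 13.3 and 22.8 (−4.81 ± 0.87). At higher levels were GATA22, a regulator of greening (AT4G26150, chromosome 4, 13253210 to 13254904; 16.2 and 30.7 against 2.96 and 3.85 CPM, 2.78 ± 0.42) and the F-box gene SKIP25 (33.8 and 56.3 against 11.8 and 9.09, 2.11 ± 0.37). So were SAUR72 (5.53 against 0.565, 3.28 ± 0.62) and HSFB2A (18.6 and 20.1 against 6.01 and 5.10, 1.80 ± 0.35).

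edgeR called 0 genes, with 1696 at an unadjusted p under 0.05 and an adjusted p of 0.548 for each gene named in the previous sentences. DESeq2 called 89 higher and 102 lower, and limma called 0, with 1514 at an unadjusted p under 0.05. edgeR called 1 gene without wild-type library 2, and 1 without either library of generation 2. Both libraries lay above both wild-type libraries for 21.1% of the genes and below both for 22.2%, against 16.7% by chance.

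Further DESeq2 calls with small edgeR p were AT2G04795 (12.3 ± 0.14 against 2.18 ± 0.66 CPM, mean ± SD, 2.49 ± 0.42), CYP71B36 (2.15 ± 0.40), the methyl esterase gene MES9 (2.90 ± 0.55), PDX1L4 (3.28 ± 0.63), AT4G21740 (1.57 ± 0.31) and ATL74 (7.67-fold when summed with AT5G01881, which it overlaps). At lower levels were AT3G46370 (12.6 against 57.0 CPM, −2.18 ± 0.34), XDH2 (−4.14 ± 0.70), AT1G63240 (−2.20 ± 0.40), AT2G28360 (−2.83 ± 0.52), AT3G22142 (−5.53 ± 1.01) and AT4G17140 (−4.60 ± 0.85). HTT1 was at 0.597 and 0.292 CPM (0.95 ± 0.74), HTT2 at 9.77 (0.19 ± 0.33), HTT3 at 0.966 (−0.31 ± 0.56) and HTT4 at 0.0663 and 0.146, while HTT5 was at 0 and 0.535 against 0 (at least 3.94-fold).

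In generation 3, 9 lists passed by camera, each with an adjusted p of 0.790 with an estimated correlation. RNA silencing genes fell as a group, with a median of −1.02, 19 of 22 negative and 17 below both wild-type libraries (camera adjusted p = 0.000217, adjusted p = 0.790 with an estimated correlation, 0 adjusted over the list alone). NRPE1, a subunit of RNA polymerase V, was at 0.464 and 2.04 CPM against 9.99 and 6.54 (−2.69 ± 0.92). DCL3 was at 0.730 and 3.11 against 9.68 and 12.1 (−2.48 ± 1.11), and AGO1 at 64.5 and 64.6 against 115 and 127 (−0.90 ± 0.42). H3K27 methylation and demethylation had a median of −0.47 (0.0241 by camera) with the chromatin remodeller BRM at 7.76 and 35.1 CPM against 92.5 and 83.2. Cell division had a median of −0.76, 8 of 9 negative (0.0217), with MCM2 at 1.66 and 4.96 against 11.8 and 7.09. Photosynthesis had a median of 0.39, 23 of 26 positive (0.0241). Its member LHCB1.2 was at 12290 and 4642 CPM against 9392 and 9978, library 1 above and library 2 below both wild-type libraries. Library 1 of generation 3 has fewer counts for long genes, and without it camera adjusted p was 0.0573 for RNA silencing, 0.444 for H3K27, 0.117 for cell division and 0.729 for photosynthesis. With a length offset these were 0.102, 0.0751, 0.00929 and 0.205 (range over 5 alternatives 9.38e-06 to 0.660, 0.0228 to 0.811, 0.00415 to 0.235 and 0.205 to 0.972). With the length slope as covariate 0 of these 4 calls were kept (0.660, 0.811, 0.175 and 0.805), and photosynthesis then had a downward test. Without library 1 of generations 2 and 3 that of RNA silencing was kept (0.0138) and the others were lost (0.259, 0.235 and 0.771). With a length offset as well all 4 were lost (0.618, 0.627, 0.221 and 0.972, photosynthesis with a downward test). With a clock index as covariate photosynthesis was lost (0.212). Cell division was also lost without wild-type library 1 (0.517), and H3K27 and photosynthesis without wild-type library 2 (0.146 and 0.712). The 10 fits ranged from 4.21e-06 to 0.0573, 0.00792 to 0.444, 0.000247 to 0.517 and 0.000122 to 0.729 in the same order of lists.

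Salicylic acid and immunity genes had a median of 1.14 with 24 of 30 positive and 14 above both wild-type libraries (0.00144 by camera). PR1 was at 49.3 and 27.7 CPM against 0 and 1.34 and PR5 at 158 and 83.3 against 12.1 and 14.6 (3.18 ± 0.93, called by DESeq2). Flavonoid genes had a median of 2.22 with 8 of 8 positive (0.00434), CHS, the entry enzyme of the pathway, being at 31.7 and 573 CPM against 78.2 and 1.53. The senescence median was 0.86 (0.00651), the cold and abscisic acid median −1.58 with 14 of 19 negative (0.00622). COR15A was at 27.4 and 22.2 CPM against 60.4 and 116 and RD29A at 8.89 and 27.3 against 28.5 and 749. The meristem marker median was 2.57, or 1.65 at the bound, with 4 of 4 positive (0.0387). In these 5 lists 0 members were called adjusted over the list alone, and with an estimated correlation the adjusted p = 0.790 for each. Wild-type library 1 carried the calls of immunity (0.349 by camera without it) and senescence (0.470), and wild-type library 2 that of cold (0.844). Library 1 of generation 3 carried those of immunity (0.0573) and senescence (0.0502), and library 2 those of flavonoids (0.408) and cold (0.110). The meristem call, which rests on 4 of 11 fixed genes, was kept in 2 of the 10 fits, those without generation 3 library 2 and sgs3-12 library 2. Camera adjusted p was 0.0769, 0.367, 0.0863, 0.0841, 0.160, 0.155, 0.590 and 0.113 without wild-type library 1 or 2, 30 °C-grown library 1 or 2, generation 2 library 1 or 2, generation 3 library 1 and sgs3-12 library 1. The 10 fits ranged from 8.26e-07 to 0.349 for immunity, 1.08e-07 to 0.408 for flavonoids, 1.58e-05 to 0.470 for senescence, 2.32e-08 to 0.844 for cold and 0.0315 to 0.590 for meristem markers. With a clock index as covariate the calls of cold (0.995, with an upward test), flavonoids (0.885) and meristem markers (0.275) were lost. With the length slope as covariate those of cold (0.325) and meristem markers (0.455) were lost. Meristem markers were also lost with a length offset (0.0593) and without library 1 of generations 2 and 3 (0.656, or 0.627 with an offset as well).

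Of 20 clock genes (median −1.61, camera adjusted p = 0.0575), 14 were called adjusted over the list alone, 4 higher and 10 lower. ELF3 was at 7.56 and 2.19 CPM against 18.3 and 79.1, LUX at 3.25 and 2.67 against 4.07 and 73.8, and RVE1 at 23.8 and 67.4 against 12.6 and 4.17. Heat shock factors (median 0.15, camera adjusted p = 0.465) had 2, 1 higher and 1 lower. The other lists of generation 3 had medians of 0.18 for heat shock proteins (camera adjusted p = 0.679), 0.13 for the unfolded protein response (0.465), 0.25 for HTT genes (0.465), 0.72 for jasmonate (0.0532), 0.37 for glucosinolate (0.206), −1.41 for iron (0.465) and −0.42 for phosphate (0.519).

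**Figure D3:**
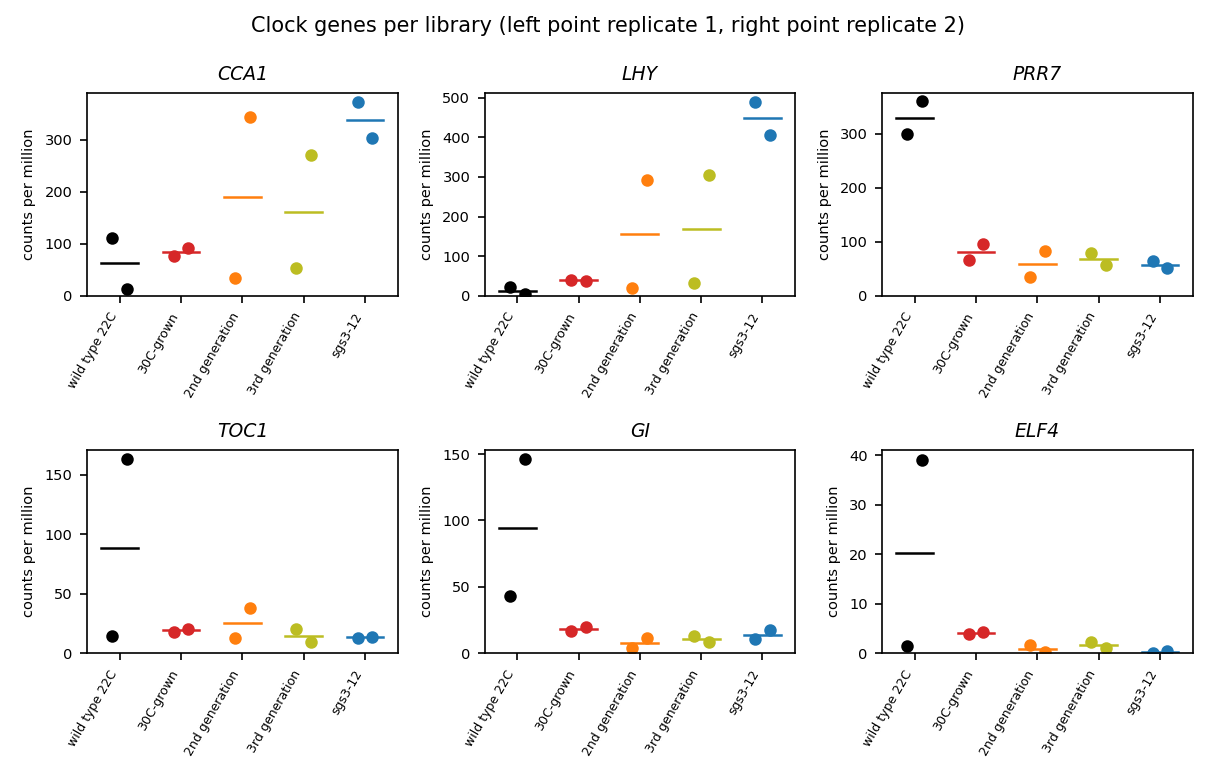
Level in CPM (y axis) of CCA1, LHY, PRR7, TOC1, GI and ELF4 in each of the 10 libraries (points) by group (x axis), with the group mean as a line. TOC1 lies at 14.3 and 163 CPM in the wild-type libraries and at 9.29 to 38.0 in the other groups, and LHY at 489 and 407 CPM in sgs3-12 against 21.6 and 4.08 in wild type.

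The fourth comparison, sgs3-12 against wild type, both unstressed, addresses which genes depend on SGS3. Of the targets of TAS small RNAs, some stood higher. HTT2 (AT5G18040, chromosome 5, 5972419 to 5974156) was at 35.9 and 41.1 CPM against 10.2 and 6.999 (log2 fold change 2.16 ± 0.35, SE, n = 2 per group), and HTT1 at 3.04 and 2.58 against 0.354 and 0.0927 (3.61 ± 0.74). The auxin response factor gene ARF4 (AT5G60450, chromosome 5, 24308322 to 24312698), a target of TAS3, was at 116 and 80.4 against 22.5 and 28.6 (1.95 ± 0.38). Other genes at higher levels, named after their values were seen, were AT3G29639 (chromosome 3, 11478732 to 11479749; 35.6 and 36.5 against 1.06 and 0.185 CPM, 5.84 ± 0.73) and the F-box gene SDC (AT2G17690, chromosome 2, 7682383 to 7684083; 20.7 ± 12.5 against 0.202 ± 0.089 CPM, mean ± SD, 6.63 ± 0.88), which is known to be silenced by DNA methylation. The transposable element gene AT2G15800 was higher too (chromosome 2, 6880825 to 6882741; 71.1 and 30.2 against 0 and 0, at least 746-fold). At lower levels were AT3G46370 (3.89 against 57.0 CPM, −3.87 ± 0.37) and PHS1 (AT3G29320; 52.6 against 574, −3.45 ± 0.46). So were the cytosolic phosphorylase PHS2 (AT3G46970; 22.7 and 24.4 against 346 and 755, −4.55 ± 0.74) and the kinase gene CIPK20 (AT5G45820; 11.3 and 10.9 against 177 and 114, −3.71 ± 0.55).

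edgeR called 0 genes and found 1959 at an unadjusted p under 0.05, the lowest adjusted p being 0.0815 for AT3G46370. DESeq2 called 276 higher and 316 lower, and limma called 5: AT3G29639 (limma adjusted p = 0.0110), AT2G15800 (0.0120), SDC (AT2G17690; 0.0489), AT2G15810 (0.0412) and AT3G46370 (0.0120), with edgeR adjusted p of 0.0815 to 0.339. AT2G15810, next to AT2G15800, was at 70.2 and 32.3 CPM against 0.442 and 0.649. For HTT2 the edgeR adjusted p was 0.266, DESeq2's 9.99e-06, and the range over the alternatives of HTT2 in sgs3-12 was 1.17e-08 to 1. The edgeR count was 5 without wild-type library 1 and 4 without either library of generation 2. Both sgs3-12 libraries lay above both wild-type libraries for 27.02% of the genes and below both for 24.6%, against 16.7% by chance.

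Other DESeq2 calls with small edgeR p were AT5G52070 (35.8 against 6.88 CPM, 2.38 ± 0.34) and the transposable element gene AT4G04293 (50.7 and 68.7 against 3.49 and 6.77, 3.54 ± 0.56). Others were MES9 (3.41 ± 0.56), AT5G19490 (3.05 ± 0.51), GATA22 (2.51 ± 0.42) and ATL74 (5.63-fold when summed with AT5G01881, which it overlaps). Transposable element genes can share reads with other copies, so their values are uncertain. At lower levels were AT3G05640 (4.53 against 33.8 CPM, −2.90 ± 0.42), AT3G01310 (−3.26 ± 0.53), GLR3.5 (−2.88 ± 0.49) and ATG4A (−2.29 ± 0.40, overlapping AT2G44130). CDA6 had 0 counts in sgs3-12 (at least 138-fold lower), and CBF3 had 0 and 1 counts there (0 and 0.0445 CPM) against 3.54 and 16.5 CPM.

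The HTT list had a median of 2.96, and 5 of 5 genes lay above both wild-type libraries (camera adjusted p = 2.83e-06, adjusted p = 0.0951 with an estimated correlation), with 2 called adjusted over the list alone. It is the only list of the 4 comparisons that also passed fry's directional test (fry adjusted p = 0.0155; 0.00880 by its mixed test). HTT3 was at 1.81 against 1.199 CPM (0.59 ± 0.55), HTT4 at 0.560 and 0.935 against 0.0442 and 0.139 CPM, and HTT5 at 0.280 and 1.07 against 0 (at least 9.94-fold). In the list of TAS3 and TAS4 targets (median 0.31, camera adjusted p = 0.212), ARF4 was called adjusted over the list alone, while ARF3 was at 30.9 against 26.1 CPM (0.24 ± 0.46) and ARF2 at 296 against 311 (−0.07 ± 0.71). The precursors TAS1A (0.34 ± 0.43), TAS1B (0.40 ± 0.44), TAS1C (0.06 ± 0.42), TAS2 (0.21 ± 0.42) and TAS3 (0.86 ± 0.51) differed by less than 2 standard errors.

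Salicylic acid and immunity genes had a median of 1.97, with 26 of 30 positive and 22 above both wild-type libraries (camera adjusted p = 2.76e-07, adjusted p = 0.656 with an estimated correlation). The marker genes PR1 (118 and 109 CPM against 0 and 1.34), PR2 (213 and 467 against 8.22 and 30.2) and PR5 (220.0 and 329 against 12.1 and 14.6, 4.36 ± 0.99) were among them. In the list 0 were called adjusted over the list alone, and DESeq2 called 3. All 12 genes of the unfolded protein response were positive, with a median of 1.68 (camera adjusted p = 4.65e-06, adjusted p = 0.620 with an estimated correlation), 1 called adjusted over the list alone. BIP3 was at 18.8 and 57.3 CPM against 0.0442 and 1.85, and ERDJ3A at 5.68 and 15.5 against 1.15 and 1.90 (2.79 ± 0.63). Heat shock proteins had a median of 1.42, or 1.38 at the bound, with 26 of 30 positive (camera adjusted p = 3.05e-05, adjusted p = 0.656 with an estimated correlation) and 0 called adjusted over the list alone. HSP70-4 was at 48.8 and 257 CPM against 8.71 and 9.04, and without sgs3-12 library 2 the list's camera adjusted p was 0.122 (range over the 10 fits 2.41e-11 to 0.122). Flavonoid genes had a median of 2.11, or 2.04 at the bound, 7 of 8 positive (camera adjusted p = 9.92e-05, adjusted p = 0.620 with an estimated correlation, 0 adjusted over the list alone). F3H was at 38.8 and 61.1 CPM against 6.54 and 2.64.

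Cold and abscisic acid genes fell as a group, with a median of −2.58 and 15 of 19 negative (camera adjusted p = 9.04e-07, adjusted p = 0.620 with an estimated correlation), 9 called lower adjusted over the list alone. COR15A, which protects chloroplast membranes in the cold, was at 6.08 and 13.9 CPM against 60.4 and 116 (−3.15 ± 0.56), COR15B at 0.480 and 1.91 against 22.2 and 223, and the regulator CBF2 at 0.200 and 0.0445 against 1.19 and 5.75. Photosynthesis had a median of −0.93, 21 of 26 negative (camera adjusted p = 0.00141, adjusted p = 0.774 with an estimated correlation, 0 adjusted over the list alone), with LHCB1.2 at 3025 and 1596 CPM against 9392 and 9978. That call was lost without wild-type library 1 (camera adjusted p = 0.586, range over the 10 fits 4.95e-08 to 0.586). The clock list had a median of −2.34 (camera adjusted p = 0.0355, adjusted p = 0.620 with an estimated correlation), 13 called adjusted over the list alone, 4 higher and 9 lower. LHY, a morning gene, was at 489 and 407 CPM against 21.6 and 4.08 (5.12 ± 1.52), and PRR7 at 63.9 and 51.3 against 299.9 and 361 (−2.52 ± 0.49). FKF1 was at 0 and 0 against 0.796 and 61.3, and the evening-peaking CCR2 at 14.4 and 15.5 against 80.9 and 3268. Camera lost the clock call without generation 2 library 1 (0.102) or 2 (0.0968) and without sgs3-12 library 1 (0.0876) or 2 (0.122), over a range of 1.08e-07 to 0.122. With a clock index as covariate the camera adjusted p of the cold list was 0.219, of flavonoids 0.834 and of heat shock proteins 0.649 (range over 5 alternatives 1.95e-06 to 0.219, 2.24e-05 to 0.834 and 1.52e-05 to 0.649), and the test of flavonoids was then downward. The clock call was lost in the other 4 of these alternatives, with a camera adjusted p of 0.0763 with a length offset, 0.293 with the length slope as covariate, and 0.206 and 0.214 without library 1 of generations 2 and 3, the latter with an offset. The clock index is made from clock genes and so does not test this list.

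Adjusted over the list alone, sgs3-12 also had SGS3 lower among RNA silencing genes (median and mean upward with a downward test, camera adjusted p = 0.905) and 2 lower oxidative stress genes, CAT1 (21.2 and 22.6 against 115 and 104 CPM, −2.32 ± 0.61) being among the DESeq2 calls. Warm-temperature growth and auxin genes had a median of −0.64 (0.0658 by camera), with PIF4, a driver of growth in warmth, at 114 and 83.2 against 290.2 and 308 CPM (−1.60 ± 0.44). Camera adjusted p and medians of the rest were 0.145 and 0.57 for senescence, 0.533 and 0.31 for jasmonate, and 0.986 and −1.46 for iron (with an upward test). They were 0.533 and 0.34 for H3K27, 0.2997 and −0.55 for cell division, 0.445 and −0.20 for phosphate, 0.533 and 0.14 for glucosinolate, 0.629 and 0.02 for heat shock factors, and 0.0703 and 2.35 (2.28 at the bound) for meristem markers.

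Direct comparisons of the generations address whether progeny differ from the heat-grown plants. A gene called by limma was AT4G36700, at 22.4 and 16.9 CPM in 30 °C-grown plants, 0 and 0.146 in generation 2 and 0 and 0.438 in generation 3. limma called it lower in generation 2 (−3.59 on log2(FPKM + 1), limma adjusted p = 0.0172) and in generation 3 (−3.50, 0.0210), and edgeR's adjusted p was 0.476 and 0.580. HTT1 was at 2.53 and 2.03 CPM in 30 °C-grown plants against 0.112 to 0.597 in the 2 progeny generations, and HSP17.6A-CI at 15.1 and 17.0 against 0.862 to 2.28. SPL4, at 1.99 and 2.24 CPM in the heat, was at 28.6 and 20.8 in generation 2 and at 20.4 and 13.4 in generation 3. edgeR called 0 genes between generation 2 and 30 °C-grown plants (1849 at an unadjusted p under 0.05), 0 between generation 3 and 30 °C-grown plants (1360) and 0 between generations 3 and 2 (328). DESeq2 called 326, 214 and 2 genes, and limma 1, 1 and 0. Without library 1 of generation 2, edgeR called 487 genes between generation 2 and 30 °C-grown plants and 252 between generations 3 and 2.

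For genes different from wild type in all 3 generations, edgeR's count was 0 in each direction, while DESeq2 called 16 higher in all 3 and 16 lower in all 3, or 14 and 16 when at least 10 counts were asked for in each raised group or in wild type. Of the higher ones, HSFB2A (1.94, 1.80 and 1.80 in generations 1, 2 and 3) and LEC (2.14, 3.23 and 2.58) were not called in sgs3-12, nor was AT2G07774. The other 13 were, among them AT1G68440 (2.62, 2.51 and 2.56, and 2.91 in sgs3-12), the myb-like gene AT1G70000 (2.19, 2.23 and 2.65, and 2.84) and AT5G19875 (2.86, 2.68 and 2.64, and 3.52). So were PDX1L4 (2.57, 2.47 and 3.28, and 3.36) and SKIP25 (1.43, 1.75 and 2.11, and 2.08). BSMT1, a salicylate methyltransferase gene, had 0 counts in wild type and was at 51.1 and 11.7 CPM in the heat, 0.393 and 3.79 in generation 2, 1.06 and 4.86 in generation 3 and 0.0800 and 3.83 in sgs3-12. ALD1 and F6'H1, also at 0 in wild type, were at 0.0846 CPM or less in the heat and at 35.4 and 14.5 CPM in library 2 of generation 2.

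The 16 lower genes included starch genes, namely PHS1 (AT3G29320; −2.21, −3.50 and −3.23 in the 3 generations, and −3.45 in sgs3-12) and GWD1 (−2.60, −4.45 and −4.27, and −3.60). Others were the branching enzyme gene SBE2.1 (−2.32, −3.24 and −3.10, and −2.88), PU1 (−1.89, −2.39 and −1.94, and −2.26) and SS4 (−1.92, −2.95 and −2.76, and −1.58, not called in sgs3-12). The wild-type libraries differed in some of these, with GWD1 at 403 and 1480 CPM and SBE2.1 at 68.7 and 289, but less in PHS1, at 588.8 and 559.5. Clock-controlled genes among the 16 also differed within wild type. FKF1 was at 0.796 and 61.3 CPM there, AT5G23240 (overlapping AT5G23235) at 2.96 and 235, AT4G33980 at 0.354 and 50.4, and PRR3 at 0.928 and 59.4. PRR7 was at 299.9 and 361 (−2.01, −2.48 and −2.26, and −2.52 in sgs3-12). AT3G46370 (57.2 and 56.9 CPM in wild type), AT4G04410 and AT5G40450 were lower in all 4 comparisons, and 12 of the 16 were also called in sgs3-12. In the simulated sets, unchanged groups shared 2 simulated wild-type libraries. These sets gave a mean of 2.65 and at most 6 genes higher in all 3, and 0.25 and at most 1 lower. Independent lists would share 0.0213 and 0.00397. Genes were drawn independently, so a joint difference of clock genes within the real wild-type pair was not reproduced. Leaving out wild-type library 2, edgeR called 1 gene higher in all 3, and leaving out generation 2 library 2, 1 lower.

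Calls of 30 °C-grown plants and sgs3-12 shared 34 higher (32 with at least 10 counts in each group) and 24 lower genes by DESeq2 and 0 by edgeR, against 4.70 and 0.450 in simulated unchanged groups and 2.83 and 1.25 for independent lists. Generations 2 and 3 shared 51 and 72 (4.95 and 1.65 simulated, 2.05 and 0.975 independent). Generation 2 and sgs3-12 shared 74 and 62 (4.85 and 1.2, 6.23 and 2.95), and generation 3 and sgs3-12 shared 66 and 45 (4.15 and 1.2, 1.29 and 1.69). All these comparisons use the same 2 wild-type libraries, which cannot be split into parts of 2, so part of each excess may come from the shared controls. The simulated sets, with genes drawn independently, do not bound that part. Across genes, which are not independent replicates, the correlation of log2 fold changes was 0.490 between 30 °C-grown plants and generation 2 (0.494 in simulated unchanged groups), 0.482 with generation 3 (0.495), 0.352 with sgs3-12 (0.496). It was 0.772 between generations 2 and 3 (0.494), 0.564 between generation 2 and sgs3-12 (0.496) and 0.581 between generation 3 and sgs3-12 (0.497). Covariances in the same order were 0.655, 0.557, 0.459, 1.01, 0.835 and 0.744, against simulated values of 0.299 to 0.304. Without generation 2 library 2 the correlation of generation 2 with sgs3-12 was 0.0993, that with 30 °C-grown plants 0.338, and without generation 3 library 2 those of generation 3 were 0.316 and 0.288. The first libraries of generations 2 and 3 correlated at 0.950 in log2 CPM. The simulated sets lack this likeness, for the correlation and for the shared calls of these generations. Without generation 2 library 1 the correlation of fold changes of generations 2 and 3 was 0.595.

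Of the lists that passed by camera in no comparison, the pentatricopeptide repeat genes targeted by TAS2 had medians of 0.36, −0.13, −0.12 and 0.27 in generations 1, 2 and 3 and sgs3-12 (camera adjusted p = 0.242, 0.862, 0.872 and 0.387). TAS precursor loci had 0.22, 0.34, 0.36 and 0.34 (0.484, 0.314, 0.307 and 0.422). TAS3 and TAS4 targets had −0.08, −0.62 and −0.52 in the generations (0.909, 0.292 and 0.465, with an upward mean and test in generation 1), and flowering genes 0.39, 0.45 and −0.37 in generations 2 and 3 and sgs3-12 (0.822, 0.731 and 0.528). Warm-temperature growth and auxin genes had 0.09, 0.48 and −0.00 in the generations (0.750, 0.962 and 0.954, with an upward mean in generation 3). Oxidative stress genes had 1.21 (1.07 at the bound), 0.88 and 0.71 (0.37 at the bound) in generations 2 and 3 and sgs3-12 (0.132, 0.128 and 0.610). Marker medians of other cell types in the order of the 4 comparisons were −0.50, −0.41, −0.20 and 0.32 for guard cells (0.286, 0.659, 0.741 and 0.533). They were −0.29, −0.23, −0.24 and −0.04 for the vasculature (0.540, 0.822, 0.679 and 0.717) and −0.82, −0.91, −0.33 and 0.31 for the epidermis (0.286, 0.292, 0.679 and 0.528), all by camera, with 4, 8 and 3 genes expressed.

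Reference genes, often used as controls for constancy, had medians of 0.02, 0.10, 0.02 and −0.07 (camera adjusted p = 0.943, 0.822, 0.943 and 0.528), with a downward test in generation 1 and a downward mean and test in generation 2. Among the remaining focal genes, MYB75, a TAS4 target, was at 1.61, 1.25, 1.13 and 0.38 on the log2 scale in the 4 comparisons, and the histone demethylase gene REF6 at −0.61, −1.31, −1.13 and 0.23. FT was at 1.93, 2.00, 1.80 and 1.44, SOC1 at −0.18, 0.44, 0.45 and −0.90. FLC was at 0.13, −3.39, −0.60 and 0.27, and TAS3 at 1.40, 1.38, 1.21 and 0.86, none called by edgeR or DESeq2. Of 8 ATCOPIA78 (ONSEN) copies, a heat-activated retrotransposon family, and of 5 root markers, 2 each had enough counts, too few for a list test. The copy AT1G11265 was at −0.70, 1.49, 0.07 and 1.25 on the log2 scale in the 4 comparisons and AT5G13205 at −1.92, 1.72, −0.14 and 1.198. The root marker PYK10 was at 1.84, −2.98, −0.20 and −1.29, and SCR at 0.28, 0.21, 0.54 and 1.22. With p adjusted over the tested root markers alone, SCR was called higher in sgs3-12 by edgeR, and DESeq2 did not call it (DESeq2 adjusted p = 0.112). The copy AT1G48710 had 0 and 6 counts in wild type, 5 and 5 in the heat, 2 and 27 in generation 2, 6 and 4 in generation 3 and 4 and 1 in sgs3-12. The copies AT3G59720, AT1G21945 and AT3G32415 had 0 in every library. The root marker EXP7 had 0 counts in every library, COBL9 at most 3 and TIP2;3 at most 1.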

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

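DESeq2, edgeR's newer method, no filter, median-of-ratios factors and length offset in edgeR, the covariate fits and the fits without library 1 of generations 2 and 3 are tests chosen after the results were seen; the other alternatives were planned. Results are given for genes called in 30 °C-grown plants (heat), generation 2, generation 3 and sgs3-12, and between groups. No named gene that edgeR or an alternative called reversed, 3 called lists changed direction in the length, clock and library 1 fits (below), and the cause was not tested for any difference below.

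Of the gene lists, edgeR with camera called 31 in all; 0 were called with an estimated correlation, 1 by fry's directional test and 4 by its mixed test. limma on log2(FPKM + 1) called 1 gene in heat, 5 in sgs3-12, 1 between generation 2 and heat and 1 between generation 3 and heat. SGS3 in sgs3-12 was −1.41 on that scale, also with a mean FPKM of 0.1, no filter, a robust fit or a replicate block. With pseudocounts of 0.1 and 0.5 limma called 1 and 3 genes in sgs3-12. With a mean FPKM of 0.1 it called 1 in heat, 18 in sgs3-12, and 1 and 1 between generations 2 and 3 and heat. With no filter limma called 25 in heat, 1 in generation 3, 37 in sgs3-12, 19 and 23 between generations 2 and 3 and heat, 1 between generations 3 and 2, and 1 higher and 3 lower in both heat and sgs3-12. Median-of-ratios and quantile scaling each gave 1 in heat, 6 in sgs3-12, and 1 and 1 against heat; a robust fit 1, 4, 1 and 1; a fold of 2 or more 1, 5, 1 and 1. Fits of only 4 libraries gave 28 in heat, 190 in sgs3-12 and 9 between generation 3 and heat.

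A replicate block gave 3 genes in sgs3-12 by limma, and 1 in generation 2 and 1 in sgs3-12 by edgeR. Differences between library 1 and library 2 correlated at −0.27 to 0.45 between groups, so the numbers do not pair the samples throughout. The highest, 0.45, was between generations 2 and 3. Their first libraries correlated at 0.950 in log2 CPM, against 0.788 within generation 2 and 0.919 within generation 3.

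DESeq2 called 278 genes in heat, 619 in generation 2, 191 in generation 3, 592 in sgs3-12, 326 and 214 between generations 2 and 3 and heat, 2 between generations 3 and 2, 16 higher and 16 lower in all 3 generations, and 34 higher and 24 lower in both heat and sgs3-12, with SGS3 at −1.75. edgeR's newer method called 2 in sgs3-12 and edgeR with no filter 1. With the length slope as a covariate edgeR called 16 in heat, 431 in generation 2, 9 in sgs3-12 and 1 higher and 1 lower in both heat and sgs3-12. With the clock index SGS3 was −1.27. The test of generation 3 cold genes turned upward (camera adjusted p = 0.995) and that of sgs3-12 flavonoids downward (0.834) with the clock index, and that of generation 3 photosynthesis downward with the length slope (0.805) or without library 1 of generations 2 and 3 and with a length offset (0.972). With both covariates SGS3 was −1.27, 2 genes were called between generation 3 and heat, and correlations of fold changes were 0.82, 0.82 and 0.75. Those correlations have no simulated value beside them, since the simulated unchanged groups were fitted with group alone.

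Without library 1 of generations 2 and 3, edgeR called 50 in heat, 1222 in generation 2, 0 in generation 3, 801 in sgs3-12, 788 between generation 2 and heat, 0 between generation 3 and the other generations, and 10 higher and 5 lower in both heat and sgs3-12, with SGS3 at −1.75. With a length offset as well these were 24, 1248, 0, 816, 748, 0, 5 and 4, and −1.82. DESeq2 on those 8 libraries called 1439, 2427, 1489 and 2563 in the comparisons with wild type, 2244, 536 and 809 between generations, 211 higher and 106 lower in all 3 generations and 313 and 181 in both heat and sgs3-12, with SGS3 at −1.76.

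Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, edgeR called 0 to 34 genes in heat, 0 to 1637 in generation 2, 0 to 1 in generation 3, 0 to 5 in sgs3-12, 0 to 487 between generation 2 and heat, 0 to 0 between generation 3 and heat and 0 to 252 between generations 3 and 2. Overlaps were 0 to 1 higher and 0 to 1 lower in all 3 generations, and 0 to 0 higher and 0 to 1 lower in both heat and sgs3-12. Correlations ran from 0.338 to 0.667 (heat and generation 2), 0.288 to 0.681 (heat and generation 3), 0.284 to 0.586 (heat and sgs3-12), 0.595 to 0.820 (generations 2 and 3), 0.0993 to 0.699 (generation 2 and sgs3-12) and 0.316 to 0.726 (generation 3 and sgs3-12). SGS3 ran from −2.01 to −1.49, and 27 to 37 lists were called.

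The named genes gave 5284 recomputed values, of which 5121 kept their sign and the others, called in neither fit, did not; 412 passed a threshold that the edgeR fit did not pass, and 734 moved by more than the spread between libraries. With 2 libraries per group, edgeR recovered 0 simulated changes at the fitted spread, so counts of 0 there (1564, 2302, 1696 and 1959 genes at an unadjusted p under 0.05 in heat, generations 2 and 3 and sgs3-12) do not bound how many genes differed.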

Other observations

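Except for the fits without library 2 of generation 2, which were planned, the tests in this part were chosen after the results were seen. Library 1 of generations 2 and 3 is not part of the comparisons of 30 °C-grown plants and sgs3-12 with wild type. Leaving it out changes the calls there only through shared estimates of the fit, such as the spread. Without library 1 of generations 2 and 3, edgeR called 50 genes in 30 °C-grown plants, among them the mitochondrial uncoupling protein gene PUMP4 (log2 fold change 5.02 ± 0.37, SE), the beta-amylase gene BAM5 (6.56), the zinc finger gene SZF1 (3.12), ERF5 (3.87), PUB20 (3.81), CML24 (2.33) and GOLS1 (3.15) at higher levels, and AT3G46370 (−3.13), CAT1 (−2.21) and AT4G04410 (−5.14) at lower levels. In sgs3-12 it called 801, among them PR5 (4.37 ± 0.32), PR1 (7.42), ELIP2 (6.51), LHY (5.13), HTT1 (3.62), HTT2 (2.17) and ARF4 (1.95) at higher levels, and SGS3 (−1.75), COR15A (−3.14), CAT3 (−2.35), PIF4 (−1.59) and ELF3 (−3.53) at lower levels. In generation 2, then 1 library assumed to vary like the other groups, it called 1222, with WRKY53 (6.25), LOX4 (7.42), LOX3 (5.63), CBP60G (4.61), JAZ1 (5.61) and EDS5 (4.73) higher and SGS3 (−1.88), EXP8 (−4.62) and SAUR21 (−2.80) lower. In generation 3, also then 1 library, it called 0, where DESeq2 on the same 8 libraries called 1489.

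Gene ontology terms of DESeq2 calls were tested by a hypergeometric test. In 30 °C-grown plants higher genes held 26 of 430 genes of the response to oxidative stress (adjusted p = 1.83e-10), 18 of 230 of the response to chitin (1.04e-08) and 14 of 234 of the response to heat (1.92e-05). In generation 2 they held 82 of 229 of the response to chitin (4.56e-75) and 45 of 199 of the response to wounding (3.58e-30). Genes such as WRKY53 (4.54 and 162 CPM) and LOX4 (1.40 and 627) stood high in library 2 of generation 2, and without it the calls of the immunity and jasmonate lists were lost (camera adjusted p = 0.230 and 0.697); the term test was not repeated without it. Lower genes held starch metabolism in 30 °C-grown plants (6 of 126, 0.0141), generation 2 (12 of 126, 6.65e-07), generation 3 (6 of 125, 0.0224) and sgs3-12 (15 of 126, 9.15e-07). They held rhythmic process in the same 4 comparisons (5, 14, 9 and 19 of 121 genes, 0.0418, 3.75e-09, 3.49e-05 and 1.83e-10), and in sgs3-12 cold acclimation (9 of 34, 9.15e-07). The 2 wild-type libraries themselves differed in the clock list (median 2.63 against 0.504 in random lists matched on expression). Of the starch genes, they differed in GWD1 (403 and 1480 CPM) and less in PU1 (53.4 and 73.1). These term tests were not repeated without a wild-type library either. Higher genes of sgs3-12 held systemic acquired resistance (13 of 200, 0.00390), and in generation 3 no term of higher genes passed (lowest adjusted p 0.297).

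The first pattern weighed was the spread of the 2 libraries of generation 2, with a biological coefficient of variation of 0.752 against 0.444 in wild type. Removing each library's trend of log2 CPM on gene length lowered it from 0.737 to 0.665, against 0.440 for wild type after the same step, so the length trend alone did not account for the spread. A harvest at different times of day could have added to it. The median absolute difference of the clock list between the 2 libraries, 1.39 against 0.98 in random lists matched on expression, lay at percentile 94.77 (SE 0.223) against a bound of 95. That zone of 2 SE around the bound was added after the value was seen, and under the plain bound the value falls short. Time of day therefore cannot be told apart from other differences between these libraries, since no harvest time is given in the sources used here. No biological explanation was tested.

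The second pattern was the distance of clock genes from wild type in the progeny and sgs3-12. After removal of the length trend, the median absolute log2 fold change of the clock list in generation 3 was 2.48 (2.58 before), so gene length was not the whole of it. The 2 wild-type libraries themselves differed in these genes by more than random lists matched on expression (percentile 100 of 10000 lists, median 2.63 against 0.504), as a harvest at different times would give. The 2 libraries of generation 3 did so too (percentile 100, median 1.56 against 0.578). Different harvest times may thus underlie part of the clock and cold list differences. The same may hold for other lists whose calls were lost with the clock index as covariate, but such a loss does not show it. The index itself differed between groups, at 2.73 and −4.11 in wild type, 8.01 and 7.63 in sgs3-12 and 2.52 to 7.09 in the others. As a covariate it can therefore take up part of a group difference, whatever the cause. The lists so lost in 30 °C-grown plants were heat shock factors, the unfolded protein response and glucosinolates. They were jasmonate and flavonoids in generation 2, and flavonoids, photosynthesis and meristem markers in generation 3. In sgs3-12 they were heat shock proteins and flavonoids. A biological difference between the groups stays open and was not tested.

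The third pattern was ATL74 and CPuORF49, at 0 in both wild-type libraries and present in the other groups. Summed with the gene each overlaps, the lowest wild-type count was 24, so the zeros may come from reads given to the overlapping gene. The summed genes still stood above wild type, with a lower median log2 fold change of 1.75 over the 4 comparisons, and folds of 5.20, 7.13, 7.67 and 5.63 for ATL74 with AT5G01881 and 2.52, 4.91, 2.702 and 4.205 for CPuORF49 with HSFB1 (30 °C-grown plants, generation 2, generation 3 and sgs3-12). edgeR adjusted p for the summed genes was 0.340 to 0.712, so this remaining difference was not called.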
